A study of Caenorhabditis elegans with 2 samples.

How the data were processed

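Gene expression in Caenorhabditis elegans was measured on 2 spotted 2-colour microarrays. Per the labels, channel 1 of each array held a common reference, messenger RNA of mixed wild-type worms, and channel 2 held messenger RNA of glp-4 worms at the L2 larval stage, from preparation 1 on 1 array and preparation 2 on the other. The labels do not say whether the preparations came from separate worm cultures, so p-values measure the spread between these 2 hybridisations, which may be technical. The number of arrays limits the precision. The dyes, growth temperature, glp-4 allele, scanner, background correction and scaling of the arrays are not given in the sources used here.

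The authors deposited 1 value per probe and array, which was read as the log2 ratio of the 2 channels. The base was taken from the values: 2 raised to the value was a multiple of 0.001 (within 0.002 of a step) for 99.1% of values on the preparation 1 array and 98.8% on the preparation 2 array. The same share was 1.14% or less for the inverse ratio, for natural logarithms and for base 10. Ratios had therefore been rounded to steps of 0.001 before the logarithm was taken, which makes the lowest ratios coarse. No dye or direction is stated. The descriptions name the glp-4 sample before the reference, and a rule fixed in advance read the ratio as likely glp-4 over reference if the major sperm protein and yolk protein lists both lay below 0 on both arrays, which they did. Both lists are therefore no independent finding. Higher and lower below refer to this likely direction, and every sign would turn if it were wrong.

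The table lists 21632 probes. The preparation 1 array had 21472 values with a median of 0.043, and the preparation 2 array had 21202 values with a median of 0.013. No intensities were used, so signal over background is unknown and no probe could be called absent or saturated. GEO's platform annotation gave 1 gene to 16450 probes, several to 247 and none to 4935. Only probes of 1 gene entered the tests. Names were updated by Entrez ID through the RefSeq table of the WBcel235 assembly, which held 16360 of these probes, and the other 90 kept the annotation's name. Chromosomes and gene spans also came from that table. Probes of a gene were averaged on each array, giving 14777 genes with a value on both arrays, of which 1447 had several probes. The probes of 174 genes differed in sign and by more than 1 log2 unit. Between probes of the same gene the median SD was 0.231 on the preparation 1 array and 0.447 on the preparation 2 array.

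Values were used as deposited, without further centring. Each gene's mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes) and Benjamini-Hochberg adjustment, with a threshold of 0.05. With 2 arrays the fit has 1 residual degree of freedom per gene and leans on a prior with 4.52 degrees of freedom. The reference counts as 1 control RNA, so its own spread is not in the test, and without swapped dyes a dye bias of a probe is not removed. Genes at least 2-fold from the reference on both arrays were counted without a test. A total of 28 gene lists, written before the data were examined, was tested with limma's camera at a preset inter-gene correlation of 0.01, as were chromosomes and the 189 gene-name families with at least 8 measured members. Camera with an estimated correlation and fry (a self-contained rotation test) were run as alternatives. Camera with an estimated correlation has 1 degree of freedom here.

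Genes are named by a rule fixed at the same time as the lists: the 12 largest mean ratios in each direction among genes past the threshold, with the same sign on both arrays and a gene name rather than a sequence name, at most 2 per name family. From each list came up to 4 members past the threshold, or the 2 largest where none passed. The rule also asked for the glp-4 gene, for which no value is given, and vars-1 is reported in addition. The tests were checked on 20 simulated tables of 14777 genes for this comparison, with 200 genes changed. The gene test recovered 11.3% of genes changed by 2 log2 units, 64.6% at 3, 93.1% at 4 and 97.5% at 5, and 11.1% of its calls were false. Camera with the preset correlation called a list shifted by 1 log2 unit in 100% of the tables, and with an estimated correlation in 0%. Genes were drawn independently in these tables, so they do not show how often preset camera falsely calls lists of correlated genes. In the data the estimated correlation was 0.68 for the major sperm protein list and 0.01 for the germ cell list. Other lists past the threshold had 1 (yolk), 0.64 (pharynx), 0.45 (sperm development), 0.27 (muscle), 0.25 (ribosomal) and 0.24 (meiosis). The rest had 0.17 (mitosis), 0.10 (eggshell), 0.02 (DNA replication), -0.03 (oocyte and maternal) and -0.04 (sheath, spermatheca and uterus). Each estimate rests on 1 residual degree of freedom. Where the correlation exceeds the preset 0.01, preset camera p-values can be too small. Alternatives covered centring, scaling, the variance model, probe handling, thresholds, each array alone and, added after the data were seen, corrections for gene span and for row order and chromosomes without chemoreceptors. Plots and closing tests used Python 3.11.15.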

Results

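The arrays compared RNA of glp-4 larvae at the L2 stage with RNA of a mixed wild-type reference. Worms with a defective glp-4 gene make few germ cells at the restrictive temperature, and the L2 is the second larval stage, before gametes or eggs are made. The group held 2 preparations, each hybridised once against the reference. Genotype and stage differ together between the channels, and no wild-type L2 sample was analysed here, so the ratios compare 2 RNA populations and do not isolate the mutation. A total of 14777 genes was measured on both arrays. Their median log2 ratio was 0.10 on the preparation 1 array and 0.02 on the preparation 2 array. The valyl-tRNA synthetase gene vars-1, on chromosome V, is not taken here as the gene mutated in glp-4 worms, for which no value is given. The log2 ratio of vars-1 was 0.58 in preparation 1 and -1.33 in preparation 2 (mean -0.37 ± 1.36, SD, n = 2, limma adjusted p = 0.738). This value does not check the labels.

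The first question was which genes differed between glp-4 L2 RNA and the reference. The yolk protein genes vit-5 and vit-2 and the eggshell gene cpg-2 were among the lowest in glp-4 L2, and the infection response gene irg-4 and sysm-1 were among the highest. By limma with Benjamini-Hochberg adjustment, 275 genes differed from the reference, 221 lower and 54 higher in glp-4 L2. All 275 had the same sign on both arrays. At an unadjusted p under 0.05 there were 2768 genes, and at the stricter adjusted threshold of 0.01 there were 0. Without a test, 1086 genes were at least 2-fold lower on both arrays and 591 at least 2-fold higher, against 363 and 265 if the arrays were independent. The arrays share the reference RNA, so some excess over independence could arise whatever the sample. The tested count was 605 after quantile normalization, 467 with each array centred and 140 with log2 ratios limited to 5 in either direction. In simulated data with 200 changed genes, drawn independently, 11.1% of the calls this test made were false. The false share among the 275 genes is not known from this, since the data differ from that setting.

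The yolk protein genes vit-5 and vit-2, made in the adult intestine, had the lowest mean log2 ratios, -7.06 ± 0.14 and -6.98 ± 0.26 (SD, n = 2 here and below; both limma adjusted p = 0.0208), which correspond to 134-fold and 126-fold lower levels. Both were at -7.16 on the preparation 1 array, its lowest value. Rounding to steps of 0.001 is coarse there, so these folds, their order and small SDs are approximate. The uterine-lumen genes ule-3 (-6.51 on both arrays) and ule-4 (-5.62 ± 0.25) were also lower. The eggshell proteoglycan gene cpg-2 (-5.45 ± 0.27) and the eggshell gene perm-2 (-5.17 ± 0.47) were lower, as were oma-2 (-5.10 ± 0.48), pos-1 (-5.09 ± 0.05) and mex-5 (-5.05 ± 0.30), which encode zinc-finger RNA-binding proteins of oocytes and early embryos. The cuticle collagen gene col-36 (-5.17 ± 0.29), stha-3 (-5.32 ± 0.68) and trcs-1 (-5.11 ± 0.14) were the other named genes of this group. Each of these had a limma adjusted p of 0.0208.

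Among higher genes, the infection response gene irg-4 had the largest mean log2 ratio, 5.21 ± 1.29 (limma adjusted p = 0.0257), which is 37.1-fold. sysm-1 was at 5.03 ± 0.08 (limma adjusted p = 0.0208) and mbug-1 at 4.49 ± 0.92. dod-21 and dod-24, named as downstream of the transcription factor daf-16, had means of 4.67 (5.73 and 3.60 on the arrays) and 3.91 ± 1.09 (limma adjusted p = 0.0356 and 0.0363). phat-4 of the pharyngeal gland was at 3.97 ± 0.59, the lipid-binding protein gene lbp-7 at 3.77 ± 0.29, and the cuticle collagen gene col-149 at 3.58 ± 0.11. The other named genes of this group were pud-4 (4.04 ± 0.55), cng-1 (3.86 ± 0.50), idpc-7 (3.81 ± 0.40) and pud-2.1 (3.70 ± 0.56). Their limma adjusted p lay between 0.0208 and 0.0363.

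**Figure D1:**
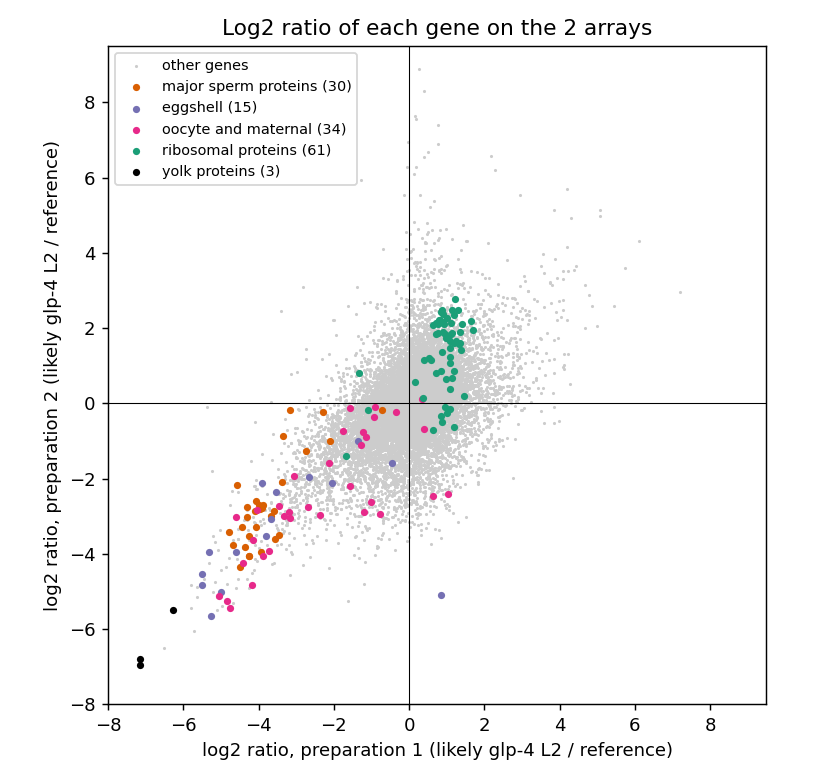
Log2 ratio of each of 14777 genes on the preparation 1 array (x axis) against the preparation 2 array (y axis), both likely glp-4 L2 over reference, with 5 gene lists in colour. Yolk genes lie at the lower left on both arrays with a median of -6.98, and ribosomal protein genes, with a median of 1.38, lie mostly at the upper right.

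The second question was which cell types and processes differed. Lists of germ cells, meiosis, gametes and eggs were lower in glp-4 L2. Of 35 germ cell genes measured, 7 were lower past the gene test, 0 were higher and 28 did not pass. Adjusted over the list alone, 25 were lower. The median log2 ratio was -1.82 (limma camera adjusted p = 1.12e-16; adjusted p = 0.698 with an estimated correlation). They included cgh-1, an RNA helicase of germline granules (-3.95 ± 0.44), pgl-1, a P granule protein (-3.11 ± 0.73), the Argonaute gene wago-1 (-2.98 ± 0.46) and iff-1 (-2.93 ± 0.60). Of 33 meiosis genes, 5 were lower and 28 did not pass. Adjusted over the list alone, 25 were lower. The median was -1.56 (limma camera adjusted p = 3.81e-16; adjusted p = 0.698 with an estimated correlation). Among them were mei-2, a katanin subunit of the meiotic spindle (-3.81 ± 0.19), the chromosome axis gene him-3 (-3.18 ± 0.26), the pairing-centre gene zim-1 (-2.81 ± 0.52) and the synaptonemal complex gene syp-2 (-2.70 ± 0.18).

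Of 34 oocyte and maternal genes, 16 were lower and 18 did not pass, and 24 were lower when adjusted over the list alone. Their median was -2.27 (limma camera adjusted p = 7.68e-19; adjusted p = 0.698 with an estimated correlation). The maternal RNA-binding protein gene spn-4 was at -4.51 ± 0.46. Of 15 eggshell genes, 8 were lower and 7 did not pass, and 13 were lower when adjusted over the list alone. The eggshell median was -3.38 (limma camera adjusted p = 1.83e-15; adjusted p = 0.698 with an estimated correlation), with cpg-3 at -5.02 ± 0.68 and cpg-1 at -5.01 on both arrays. All 3 measured yolk genes were lower, adjusted over the list alone as well, including vit-6 at -5.89 ± 0.54 (list median -6.98, limma camera adjusted p = 5.94e-07; adjusted p = 0.698 with an estimated correlation). Of 30 major sperm protein genes, 22 were lower and 8 did not pass, and 27 were lower when adjusted over the list alone. Their median was -3.43 (limma camera adjusted p = 1.00e-25; adjusted p = 0.698 with an estimated correlation). The lowest were msp-33 (-4.43 ± 0.11), msp-36 (-4.23 ± 0.64), msp-65 (-4.16 ± 0.15) and msp-57 (-4.16 ± 0.13). The msp genes are near-identical copies whose probes can bind each other's RNA, so they are not separate measurements. The yolk and msp lists also served to read the direction of the ratio and are not independent evidence of it. Of 56 other sperm genes, 3 were lower and 53 did not pass (6 lower when adjusted over the list alone). They were msd-1 (-3.03 ± 0.12), msd-4 (-2.87 ± 0.15) and sss-1 (-2.74 ± 0.41). That list's median was -0.80 over both arrays and -0.25 on the preparation 2 array alone (limma camera adjusted p = 2.18e-06; adjusted p = 0.945 with an estimated correlation). The spe name family, named for spermatogenesis, was not lower, with a median of 0.06 over 24 genes (limma camera adjusted p = 0.832). Its medians were 0.004 and 0.37 on the preparation 1 and 2 arrays, with 5 genes below 0 on both and 9 above.

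Genes of cell division were lower as lists, with few members past the gene test. The DNA replication list had 1 of 31 genes lower, the replicative helicase gene mcm-3 (-2.52 ± 0.08), and 30 did not pass. Adjusted over the list alone, 17 were lower. The median was -1.34 (limma camera adjusted p = 8.88e-11; adjusted p = 0.698 with an estimated correlation). The mitosis list had 1 of 51 genes lower, the polo-like kinase gene plk-3 (-3.91 ± 0.11), and 50 did not pass. Adjusted over the list alone, 21 were lower. The median was -1.22 (limma camera adjusted p = 5.03e-14; adjusted p = 0.698 with an estimated correlation). The list of sheath, spermatheca and uterus genes had 0 of 28 past the gene test, and adjusted over the list alone 4 were lower and 1 higher. Its median was -0.42, with -0.23 and -0.62 on the preparation 1 and 2 arrays (limma camera adjusted p = 0.0331; adjusted p = 0.698 with an estimated correlation), and camera gave an adjusted p of 0.269 after correction for gene span. The innexin genes inx-8 and inx-14 had mean log2 ratios of -2.68 ± 0.79 and -2.41 ± 0.07 (limma adjusted p = 0.0613 and 0.0549).

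Among larval and somatic lists, ribosomal protein genes were higher as a list. Their median was 1.38 over 61 genes, 0.97 on the preparation 1 array and 1.66 on the preparation 2 array (limma camera adjusted p = 1.30e-13; adjusted p = 0.698 with an estimated correlation). None of the 61 passed the gene test over all genes, and 30 were higher and 1 lower, rpl-11.1 (-1.54), when adjusted over the list alone; rpl-11.1 was singled out after its value was seen. Ribosomal protein genes are short, with a median span of 732 base pairs, and shorter genes had higher ratios on the preparation 2 array. After correction for gene span the list's median was 1.27 (limma camera adjusted p = 3.42e-12). The largest were rps-21 (2.00 ± 1.09) and rpl-11.2 (1.92 ± 0.39), with limma adjusted p of 0.135 and 0.0950. The pharynx list had a median of 1.34 over 31 genes (limma camera adjusted p = 5.77e-05; adjusted p = 0.953 with an estimated correlation). It rested on 1 array, with 2.19 on the preparation 1 array and -0.03 on the preparation 2 array. Only phat-4 passed the gene test, and 2 were higher when adjusted over the list alone. The muscle list was likewise at 1.25 and -0.15 on the preparation 1 and 2 arrays (median 0.41 over 39 genes, limma camera adjusted p = 0.0236; adjusted p = 0.978 with an estimated correlation). The giant sarcomere protein gene ttn-1 was the 1 muscle gene past the gene test, at 2.62 ± 0.37 (limma adjusted p = 0.0492), and 4 were higher and 1 lower when adjusted over the list alone.

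**Figure D2:**
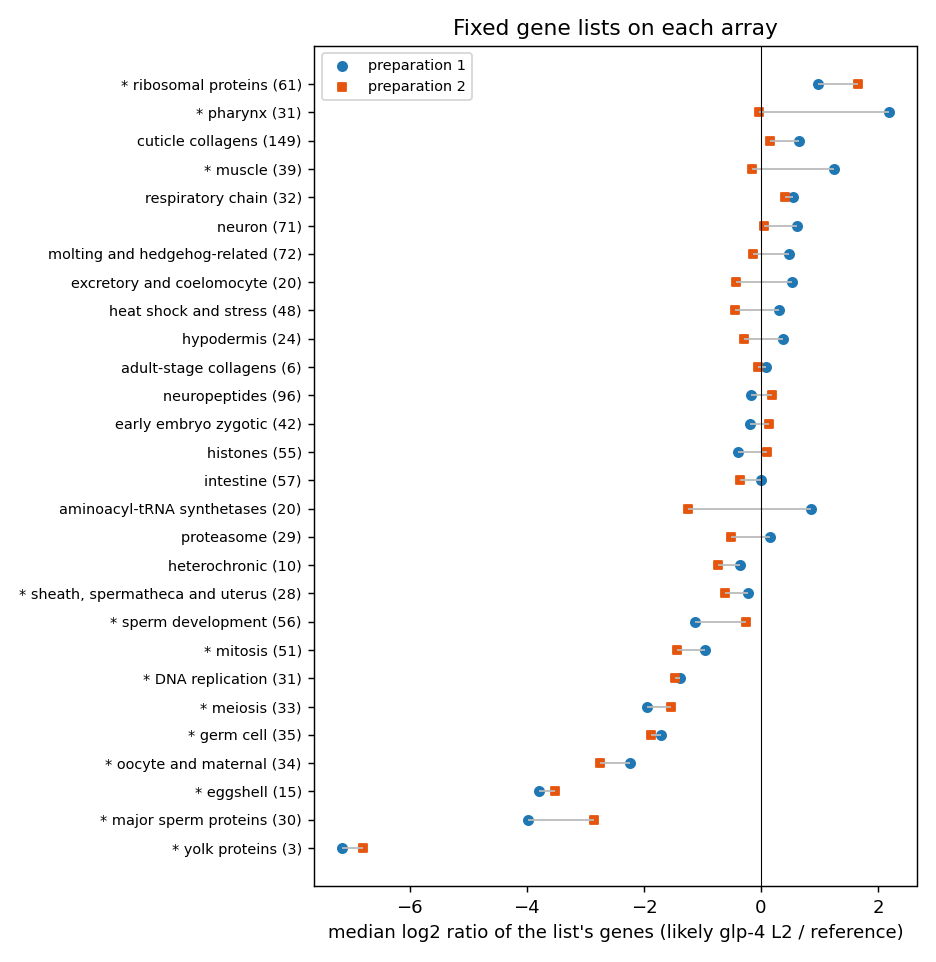
Median log2 ratio (x axis, likely glp-4 L2 over reference) of each of 28 gene lists on the preparation 1 array (circles) and the preparation 2 array (squares), with the number of measured genes in parentheses and an asterisk at a limma camera adjusted p under 0.05. Gamete and egg lists lie left of 0 on both arrays, whereas the pharynx list lies at 2.19 on one array and -0.03 on the other.

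Cuticle collagen genes went both ways. Of 149 measured, 18 were lower, 5 were higher and 126 did not pass, while 32 were lower and 38 higher when adjusted over the list alone. The list did not pass (median 0.46, with 0.65 and 0.15 on the preparation 1 and 2 arrays, mean 0.10, limma camera adjusted p = 0.175). The lowest after col-36 were col-164 (-4.48 ± 0.84), col-158 (-4.35 ± 0.31) and col-178 (-4.29 ± 0.22). Of 6 collagen genes listed for the adult cuticle, only col-19 was lower (-3.19 ± 0.13, limma adjusted p = 0.0325), also when adjusted over the list alone, and that list did not pass (limma camera adjusted p = 0.642). In the molting and hedgehog-related list the ground-like genes grl-20 (-3.24 on both arrays), grl-17 (-2.88 ± 0.58) and grl-9 (-2.61 ± 0.15) were lower, and 69 of 72 genes did not pass. Adjusted over the list alone, 7 were lower and 1 higher, and the list did not pass (limma camera adjusted p = 0.923).

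In the heat shock and stress list the small heat shock protein genes hsp-12.6 (-4.82 ± 0.03), sip-1 (-4.61 ± 0.37) and hsp-12.3 (-3.35 ± 0.55) were lower, and 45 of 48 genes did not pass (3 lower and 3 higher when adjusted over the list alone). The neuron list had 2 of 71 genes lower, also when adjusted over the list alone. They were tbh-1 (-3.24 ± 0.03) and tdc-1 (-2.71 ± 0.49), which encode enzymes of octopamine and tyramine synthesis and are also made in cells of the somatic gonad. Of 57 intestine genes, lbp-7 and the peptide transporter gene pept-1 (2.76 ± 0.33) were higher and 55 did not pass (3 higher and 3 lower when adjusted over the list alone). Of 42 early embryo genes, sdz-27 (-2.86 ± 0.43) and pes-2.1 (-2.77 ± 0.32) were lower and 40 did not pass (3 lower and 1 higher when adjusted over the list alone). The nuclear receptor gene nhr-73 (3.16 ± 0.12) was the 1 of 24 hypodermis genes past the test, also when adjusted over the list alone. None of these 5 lists passed (limma camera adjusted p of 0.642, 0.328, 0.761, 0.642 and 0.970 in this order). Medians and means differed in sign in the heat shock (0.08 and -0.24), early embryo (0.01 and -0.12), adult collagen (0.03 and -0.45), neuropeptide (0.01 and -0.03) and molting lists (0.18 and -0.02). Camera's direction had the sign of the mean in all of these but the molting list. Camera compares a list with the other genes rather than with 0, so its direction can differ from that sign.

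The remaining 7 lists passed neither test over all genes. Limma camera adjusted p was 0.842 for neuropeptides, 0.842 for excretory cells and coelomocytes, 0.137 for heterochronic genes, 0.386 for aminoacyl-tRNA synthetases, 0.175 for the proteasome, 0.425 for the respiratory chain and 0.761 for histones. Adjusted over the list alone, 0 genes passed in any of them except the synthetases, where nars-1 (1.77 ± 0.06) was higher and lars-1 (-2.39 ± 0.27) lower, both at a limma adjusted p over all genes above the threshold (0.103 and 0.0587). The synthetase medians were 0.86 on the preparation 1 array and -1.25 on the preparation 2 array. The largest mean ratios in the others were those of nlp-32 (-2.60 ± 0.80) and ins-26 (2.23 ± 0.58), clh-3 (-1.29 ± 0.77) and unc-122 (0.94 ± 1.28), hbl-1 (-1.39 ± 0.67) and lin-66 (-1.35 ± 0.54), rpn-2 (-2.47 ± 1.51) and pas-7 (-1.49 ± 0.19), sdha-2 (-2.35 ± 0.98) and ucr-2.3 (-2.19 ± 0.18), and his-39 (2.31 ± 1.89) and his-64 (1.71 ± 3.40).

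A search over 189 gene-name families found 32 past the threshold by limma camera, 24 higher and 8 lower (0 with an estimated correlation, lowest adjusted p = 0.964). Beyond the msp and ribosomal protein families, the UDP-glucuronosyltransferase family ugt was higher, with a median of 0.85 over 62 genes, 0.43 on the preparation 2 array alone, and 3 genes past the gene test (limma camera adjusted p = 1.56e-07; adjusted p = 0.964 with an estimated correlation). Chemoreceptor families made up 15 of the 24 higher ones, out of 20 tested. The medians of srh, str and srd were 0.53, 0.52 and 0.66 (limma camera adjusted p = 4.78e-06, 1.90e-05 and 4.78e-06), with srd at 0.44 and 0.93 on the preparation 1 and 2 arrays. C-type lectin genes (clec) had a median of 0.37 over 200 genes (limma camera adjusted p = 0.0112). In the gene test, however, 2 of them were higher, 4 were lower and 194 did not pass. Lower families included the nucleoporin genes npp, with a median of -1.10 over 21 genes, and the ubiquitin-ligase adaptor genes skr, with a median of -1.24 over 16 (limma camera adjusted p = 1.39e-05 and 0.0127). On the preparation 1 and 2 arrays npp was at -0.63 and -1.51 and skr at -1.34 and -0.69.

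By chromosome, medians were higher on V (0.26 over 3788 genes) and X (0.21 over 2208) and lower on I (-0.12 over 1990) and III (-0.13 over 1897). On the preparation 1 and 2 arrays the medians were 0.21 and 0.24 for V, 0.35 and 0.04 for X, -0.08 and -0.16 for I, and -0.03 and -0.22 for III. These 4 had limma camera adjusted p of 0.0438, 0.0469, 0.0438 and 0.0469 (0.327, 0.427, 0.327 and 0.327 as adjusted p with an estimated correlation). Chromosome V carried 721 of 1033 chemoreceptor genes. Without these genes its median was 0.16, whereas those of X (0.19), I (-0.14) and III (-0.14) stayed near their values with them. No chromosome then passed (limma camera adjusted p of 0.121 for V, 0.0581 for X, 0.113 for I and 0.121 for III). Chromosomes II and IV and the 2 mitochondrial genes did not pass (limma camera adjusted p of 0.645, 0.184 and 0.158).

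The third comparison was between the 2 preparations. Across genes, which are not independent replicates, Pearson's r was 0.53 and Spearman's rho 0.46. The difference between the arrays had an SD of 1.12, or 0.789 per array if both had equal error. Between probes of a gene the median SD was larger on the preparation 2 array (0.447 against 0.231). The sign was the same on both arrays for 67.8% of genes. Among the 1677 genes at least 2-fold from the reference on both arrays, a selection that raises agreement, r was 0.92. Ratios on the preparation 2 array were lower in genes of longer span (Spearman's rho across genes -0.25), from a median of 0.36 in the shortest eighth of protein-coding genes to -0.37 in the longest. On the preparation 1 array rho was 0.05. A difference of over 4 log2 units between the arrays was seen in 53 genes, 40 of them higher on the preparation 2 array.

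**Figure D3:**
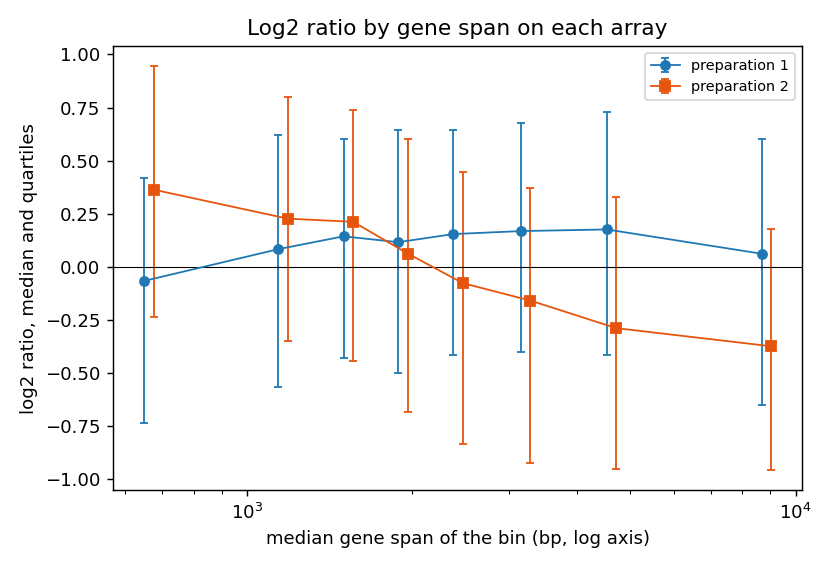
Median log2 ratio (y axis, bars give the quartiles over genes) of protein-coding genes in 8 bins of gene span (x axis, base pairs, log scale) on the preparation 1 array (circles) and the preparation 2 array (squares). The preparation 2 medians run from 0.36 to -0.37, and those of preparation 1 stay between -0.07 and 0.18.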

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

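The corrections for gene span and for row order and the chromosomes without chemoreceptors were chosen after seeing the data. No paired analysis was possible because there is only 1 group. The count of 275 genes (54 higher, 221 lower) became 467 (90 and 377) with each array centred on its median, 605 (158 and 447) after quantile normalization, 567 (124 and 443) after median centring with a common spread and 498 (113 and 385) after the correction for gene span, and each of these kept all 275. It became 140 (25 and 115) with log2 ratios limited to 5 in either direction and 146 (26 and 120) with treat at 0.5. At an adjusted p of 0.01 it was 0 (0 and 0), and genes with exactly 1 probe gave 34 higher. With 1 array left no test exists, and single arrays had 4034 to 4587 genes beyond 2-fold, 1967 to 1994 higher and 2067 to 2593 lower, against 1677, 591 and 1086 on both. At 3-fold on both arrays there were 710, with 197 higher and 513 lower. The correlation of the arrays was 0.918 among genes 2-fold on both. Camera with an estimated correlation and fry each left 0 of 13 lists (lowest adjusted p = 0.698 and 0.186, with 0 and 6 lists at an unadjusted p under 0.05). The estimated correlation also left 0 of 32 families and 0 of 4 chromosomes. Both tests have 1 residual degree of freedom, and the first also missed every simulated list shifted by 1. Of 4 chromosomes, 2 (I and V) passed after quantile normalization, with III at -0.12 and X at 0.21 (both adjusted p = 0.0512). After the span correction 0 passed, with V at 0.26, X at 0.27 and I at -0.08 (each adjusted p = 0.0506) and III at -0.07 (0.0756). Without chemoreceptors 0 passed, and V went to 0.16 while X (0.19), I (-0.14) and III (-0.14) stayed near their medians. On single arrays the muscle median ranged from -0.15 to 1.25 and the pharynx median from -0.0267 to 2.19, both lowest on the preparation 2 array. Lists that did not pass also had opposite signs on the preparation 1 and 2 arrays: synthetases (0.86 and -1.25), excretory cells (0.53 and -0.43), heat shock (0.30 and -0.45), hypodermis (0.38 and -0.28), proteasome (0.15 and -0.51), molting (0.48 and -0.13), histones (-0.39 and 0.10), neuropeptides (-0.17 and 0.18), early embryo (-0.19 and 0.13) and adult collagens (0.09 and -0.04). Under scalings and corrections some of these changed sign: early embryo (-0.0055 after quantile normalization, -0.0500 centred, -0.0304 span-corrected, -0.0035 with row blocks centred), adult collagens (-0.0260 centred), neuropeptides (-0.0474 centred, -0.0830 with row blocks centred) and heat shock (-0.11 with row blocks centred). The cause was not tested. The sheath, spermatheca and uterus list lost its call with row blocks centred, where its median of -0.49 was no smaller than the -0.42 reported (adjusted p = 0.0503), and with the span correction, where the median shrank to -0.20 (adjusted p = 0.269), and camera on ranks brought in the collagens (adjusted p = 0.0431). Robust eBayes put mcm-3, ttn-1 and tdc-1 at an adjusted p of 0.0501. The scalings and corrections brought nlp-32, ins-26, inx-8, inx-14, lars-1, rpn-2, sdha-2 and ucr-2.3 past the threshold, each in at least 1 of them. On the preparation 1 array alone vars-1 (0.58) and his-64 (-0.69) had the opposite sign to their means, neither being past the threshold, and no other named gene changed sign under the alternatives run on it. Signal over background, which limits all ratios, is unknown.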

Other observations

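Tests of the gene span pattern within lists and by larval timing, and of the chemoreceptor pattern with pseudogenes, neuron genes and peptide genes, were chosen after the result was seen. A list of dod and irg genes, drawn up after irg-4 and dod-21 had been seen, had 4 of 18 genes higher (irg-4, dod-21, dod-24 and dod-17), 2 lower (dod-23 and dod-3) and 12 that did not pass, with a median log2 ratio of 1.43. No test of this list is given, since its highest genes prompted it. In the family search neither dod nor irg passed (limma camera adjusted p = 0.152 and 0.161). Small families that passed in the search were nspb, of nematode-specific peptides (median 1.65 over 9 genes), and cutl, of cuticlin-like proteins (0.51 over 23). The autophagy family atg (-1.06 over 8) and the him family, named for meiotic chromosome loss (-1.18 over 10), were lower. Their limma camera adjusted p was 0.000442, 0.00970, 0.0124 and 0.00149 in this order, and 0.964 for each as adjusted p with an estimated correlation. The abu family, expressed in the pharynx, had medians of 3.25 on the preparation 1 array and 0.03 on the preparation 2 array.

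Of 4931 probes with several gene names or none that were measured on both arrays, 484 were at least 2-fold lower on both and 163 at least 2-fold higher. There were 16 genes above 5 log2 units on the preparation 2 array and within 1 of 0 on the preparation 1 array, and 0 in the opposite case.

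The difference between the preparations followed gene span, with a rank correlation of 0.288 across 14701 genes. Drift along the table's row order is argued against as the whole source, since the correlation was 0.262 after both arrays were centred on blocks of 200 rows. Larval timing as the whole source is argued against within 3 lists only, and only if genes of 1 molecular machine move together whatever their length. The lowest correlation among the ribosomal, respiratory chain and proteasome lists was 0.476. Within these 3 lists the pooled correlation was 0.601 (permutation p = 0.0001, the smallest that 10000 permutations can give), which is consistent with length-dependent recovery of RNA or cDNA on the preparation 2 array as a hypothesis. Other sets differed as groups between the preparation 1 and 2 arrays, such as abu (medians 3.25 and 0.03) and the synthetases (0.86 and -1.25). Timing as a part of the difference therefore stays open. Gene span includes introns and stands in for transcript length, and why 1 array is affected stays open.

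Chemoreceptor genes as 1 set had a median log2 ratio of 0.49 over 1033 genes, 0.34 and 0.59 on the preparation 1 and 2 arrays, with 713 above 0 on both and 1 past the gene test, srb-13, which was lower (-3.58). Gene span as the whole source is argued against, since the median stayed 0.357 above that of all genes after correction (95% bootstrap interval over genes 0.322 to 0.392). Before correction the excess was smaller on the preparation 1 array, where all genes had a median of 0.10, than on the preparation 2 array (0.02). The intervals given here resample genes as if independent and leave out the spread between the 2 arrays. A larger share of neurons in the L2 animals stays open, since the result for the 71 neuron genes depended on the correction for gene span: they lay below the chemoreceptors without it (difference -0.166, 95% interval -0.479 to -0.0110) and not detectably apart with it (difference 0.0269, 95% interval -0.299 to 0.192), while the 22 FMRFamide-like peptide genes lay below them without it (-0.502, 95% interval -0.908 to -0.316) and with it (-0.556, 95% interval -0.875 to -0.312). A bias of spots with little signal stays open as well: 503 pseudogenes outside these families were above 0 (median 0.28) but below the chemoreceptors (difference -0.212, 95% interval -0.275 to -0.148), and without intensities it is unknown how far pseudogenes stand for dim spots. The difference in stage between the channels stays open and untested.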
